A study of Rattus norvegicus with 18 samples.

How the data were processed

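Whole kidneys of 18 rats, 9 Dahl S and 9 S.SHR(2), were profiled with 1 Affymetrix Rat Genome 230 2.0 array each. Per the labels' protocols, total RNA was extracted with Trizol and purified on RNeasy columns, 10 µg of it was labelled as biotinylated cRNA, and 15 µg of cRNA was hybridised. Strain was taken from the labels of each sample. The design text speaks of male rats at 4, 12 and 20 weeks, 3 per strain and age, whereas the labels give an age for 2 samples and none for the other 16, so no sample was placed in an age group. The diet, 0.3% salt, is likewise labelled for those 2 rats. Replicate numbers only name the rats within a strain and pair nothing. Each sample title carries a code of its own, and rats were treated as the replicates.

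The values used were the intensities the authors deposited, 1 per probe set and array, on a linear scale with 1 decimal. Their scale was read from the values: the mean after trimming 2% from each end lay between 150.046 and 150.054 on every array, and no value was negative, while 39 were 0. The software that made and scaled them is not given in the sources used here. No scanner files or detection calls were used here, so background correction, detection filters and a block for the slide or scan date were not run. Medians of the arrays as deposited, on the log2 scale, ran from 5.84 to 6.08.

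The 57 control probe sets were left out, which left 31042. Values were transformed as log2(intensity + 16), so a fold change is on that scale and understates the change of dim genes. The array medians spanned 0.235, above the limit of 0.2 fixed for this purpose, and quantile normalization between arrays was therefore applied. The 40% of probe sets with the lowest mean over all arrays (under 5.48) were left out, and 18625 were tested. Arrays correlated with one another at 0.941 to 0.987 across probe sets.

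Strains were compared with limma (version 3.58.1, R 4.3.3), using lmFit and eBayes with an intensity trend, S.SHR(2) minus Dahl S, two-sided, without covariates. P values were adjusted by the Benjamini-Hochberg method over the probe sets or genes tested, and a call is an adjusted p under 0.05. Adjusted p values in the text are from this model unless another test is named. Errors of log2 changes are standard errors from the model, and errors of intensities are SDs over 9 rats of the deposited values. The p values given for single called genes are adjusted over genes, and those for further probe sets over probe sets.

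Probe sets were named from the platform annotation, in which 20826 named 1 gene, 436 named several and 9780 named none. Of the 20826, 20758 matched the gene table of the assembly GRCr8, which gave current symbols, chromosomes and gene order. No build is named with the values, so no coordinates are given. A gene was represented by its brightest probe set naming it alone, and 10483 genes were tested, 10450 of them with a chromosome.

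Genes past the threshold on chromosome 2 were set against those on the other chromosomes with a two-sided Fisher's exact test over the genes tested. Gene lists, 29 in number, were tested with limma's camera at a preset correlation of 0.01 where at least 5 members were tested, which held for 26. Camera with an estimated correlation, fry, and exact permutation tests of list scores over all 48620 splits of the rats were run beside it. A list score is the mean over members of the log2 value centred on the mean of all arrays. Of the 26 lists, 8 passed with the preset correlation, and the chromosome 2 candidates alone passed with an estimated correlation, by the directional test of fry and by the score test after adjustment. By the test of fry for changes in either direction, the oxidative stress list passed as well (adjusted p = 5.0e-06, against 5.0e-07 for the candidates).

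The design, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined. The rule took up to 12 called genes with the largest rise and up to 12 with the largest fall, each measured member of the list of chromosome 2 candidates, up to 4 members of each list by smallest p, and up to 6 called genes of other chromosomes. Genes outside the rule are marked in the text as chosen after their values were seen.

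The fit was tested on simulated data with 200 of 18625 probe sets changed in each of 5 runs. It recovered 46.2% of changes of 0.5 and 92.6% of changes of 1.0 on the log2 scale, with 0.8 false calls per run. Alternatives were pseudocounts of 1 and 64, no filter or a 60% filter on dim probe sets, values as deposited, arrays centred on medians, eBayes without trend or robust, array weights, 1 or 3 residual components as covariates, the mean of a gene's probe sets, an adjusted p of 0.01, a minimum of 1.5-fold, and each rat left out in turn. Fits without the 2 arrays of highest GAPDH 3′/5′ ratio and with the beta-actin ratio as a covariate were added after the data were seen. Figures were drawn with matplotlib 3.10.9.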

Results

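Kidney mRNA was measured in 18 rats, 9 of the Dahl salt-sensitive strain (Dahl S) and 9 of the congenic strain S.SHR(2), with 1 Affymetrix Rat Genome 230 2.0 array per rat. Dahl S is an inbred rat that develops hypertension and kidney damage, and the labels describe S.SHR(2) as a congenic strain made from Dahl S and the spontaneously hypertensive rat (SHR). Its name places the introgressed SHR segment on chromosome 2, and the series title calls the congenic protected in the kidney. The design text names rats of 4, 12 and 20 weeks, with 3 of each strain at each age, but the labels used here give an age for 2 rats only, both Dahl S. Age therefore entered no comparison, and whether the strain difference changed with age was not tested. The question that could be addressed was which kidney transcripts differed between the strains over all 18 rats. The deposited intensities had the same trimmed mean on every array, 150 units, and no pair of arrays was identical. The number of arrays limits the precision of each value.

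In the fit without covariates 6 genes differed between the kidneys of the strains, and the named genes with the largest changes lay on chromosome 2. The count depended on the model, with 19 genes under array weights, 29 with 1 residual component as a covariate and 107 with 3. Pla2g12a, which encodes a secreted phospholipase A2, was 2.20-fold higher in S.SHR(2) (log2 change 1.14 ± 0.087 SE, limma adjusted p = 2.2e-07). Its intensity was 99.3 ± 14.8 in Dahl S and 233 ± 23.1 in S.SHR(2) (SD, n = 9 each). Celsr2, an adhesion receptor of the cadherin superfamily, was 2.00-fold higher (0.998 ± 0.146, adjusted p = 0.0027). The mu-class glutathione S-transferases Gstm7 and Gstm1, which conjugate glutathione to electrophiles, fell by 1.38 ± 0.120 and 1.33 ± 0.167 on the log2 scale (adjusted p = 1.1e-06 and 3.8e-04).

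Gstm7 intensity was 149 ± 33.2 in Dahl S against 45.5 ± 11.3 in S.SHR(2), and Gstm1 intensity was 294 ± 81.6 against 105 ± 29.2 (SD, n = 9 each). Chd1l, a chromatin remodelling enzyme on chromosome 2, fell by 0.47 ± 0.076 (adjusted p = 0.0093), a call that was lost when arrays were centred on their medians (log2 change −0.38, adjusted p = 0.19). Wsb1, a substrate receptor of a ubiquitin ligase, was the only called gene on another chromosome, chromosome 10. It fell by 0.48 ± 0.075 (adjusted p = 0.0046), and its intensity was 603 ± 48.4 in Dahl S and 431 ± 48.2 in S.SHR(2) (SD, n = 9 each). For Pla2g12a, Gstm7, Gstm1, Chd1l and Wsb1 the ranges of the strains did not overlap, whereas those of Celsr2 did. Members of the Gstm family are close in sequence and no probe sequences were used here, so signal shared between paralogs cannot be separated and the value of each Gstm gene is uncertain.

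**Figure D1:**
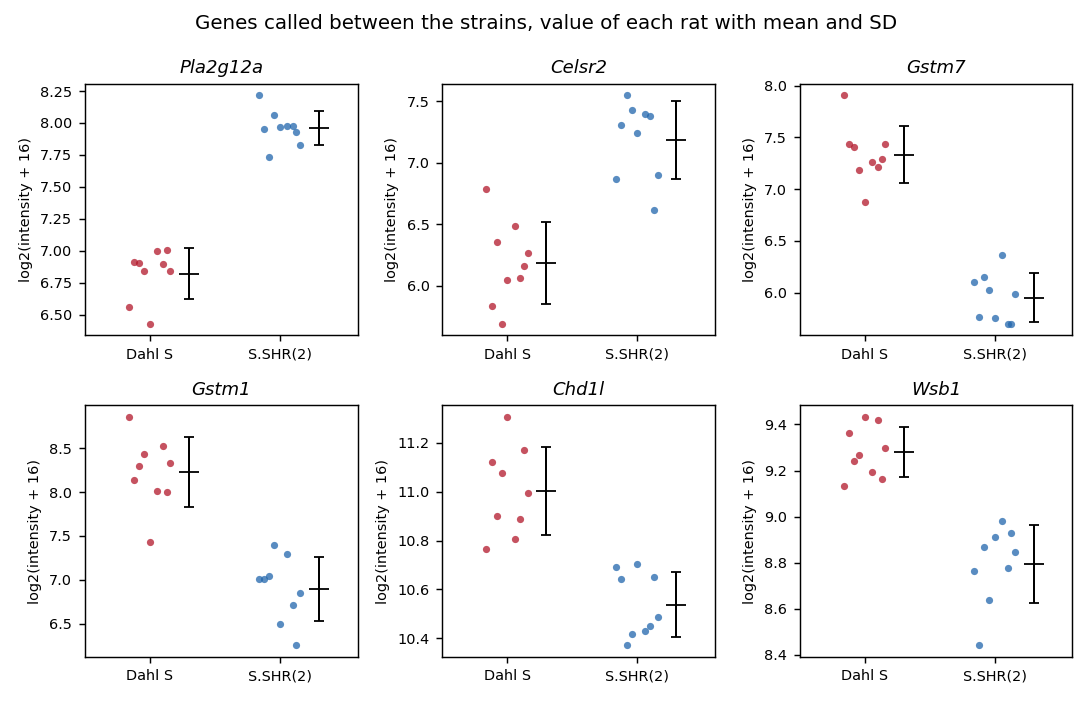
Normalized log2(intensity + 16) of the 6 called genes in each of 9 Dahl S (red) and 9 S.SHR(2) (blue) kidneys; each point is 1 rat and the black bars show mean and SD. Pla2g12a and Celsr2 were higher in S.SHR(2) and the other 4 genes were lower, with overlapping ranges for Celsr2.

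These were the 6 genes past an adjusted p of 0.05 among 10483 tested, 2 higher and 4 lower in S.SHR(2), and 443 genes had an unadjusted p under 0.05. Over probe sets, 23 of 18625 passed, 4 higher and 19 lower, and 748 had an unadjusted p under 0.05. With arrays centred on their medians the split was 7 higher and 14 lower over probe sets, but 5 higher and 3 lower over genes, and with 3 residual components 54 genes were higher and 53 lower. The balance of directions over genes therefore depended on the processing. Of the 23, 18 differed by at least 1.5-fold, and 16 had separate ranges in the strains. Over all 18625 tested, 19 probe sets had separate ranges, against 0.766 expected by chance. In data simulated for this comparison over 18625 probe sets, the test recovered 92.6% of changes of 1.0 and 46.2% of changes of 0.5 on the log2 scale. Changes of the smaller size were thus often missed there. With 1 and 3 residual components the test recovered 65.2% and 82.6% of them, with 1.8 and 9.6 false calls per run against 0.8 without. Of the unchanged probe sets 1.05% had an unadjusted p under 0.05 without components, 2.01% with 1 and 5.04% with 3. The p values of the fit without covariates were thus too large in these simulations. The simulated data were built from these same 3 residual components, which hold no strain difference by construction, and independent noise. The gain with components was therefore set by that design and does not show how such fits do on the real arrays.

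Several further genes of chromosome 2 were called through a probe set that was not the brightest for the gene or that passed only in the count over probe sets. They fall outside the rule for named genes and are given after their values were seen. Mecom, a zinc finger transcription regulator, was lower by this measure (log2 change −1.63 ± 0.136 SE, adjusted p = 6.1e-07), as were Tiparp, an ADP-ribosyltransferase (−1.58 ± 0.240, adjusted p = 0.0025), and Slc33a1, an acetyl-CoA transporter (−0.86 ± 0.165, adjusted p = 0.037). The brighter probe set of Mecom differed by −0.18 ± 0.152, that of Tiparp by 0.01 ± 0.075, and the other probe sets of Slc33a1 by 0.02 and 0.00. Ppm1l, a protein phosphatase, gave −0.46 ± 0.087 with its called probe set (adjusted p = 0.030) and −0.03 ± 0.106 with the other. Gucy1b1, a subunit of the nitric oxide receptor guanylate cyclase, gave −0.78 ± 0.117 (adjusted p = 0.0025) and −0.51 ± 0.118. Dclk1, a microtubule-associated kinase, gave −0.58 ± 0.115 (adjusted p = 0.049) and −0.30 ± 0.104. The other probe set of Chd1l was called as well (−0.62 ± 0.094, adjusted p = 0.0027). Etfdh, the dehydrogenase that passes electrons from fatty acid oxidation to ubiquinone, was higher by 0.34 ± 0.067 (adjusted p = 0.042). The calls of Slc33a1, Dclk1 and Ppm1l were lost in 13, 15 and 8 of the 18 fits that left out 1 rat each.

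The remaining 9 called probe sets named no single gene in the annotation used here. Of these, 8 were lower and 1 was higher in S.SHR(2). Among the lower ones was 1377133_at (adjusted p = 5.8e-07), whose intensity was 118 ± 41.2 in Dahl S and 12.7 ± 6.36 in S.SHR(2) (SD, n = 9 each). Its mean in S.SHR(2) lay under the pseudocount of 16, so the size of this fall depends on the pseudocount, and signal above background was not shown there. The probe set 1373053_at was higher by 0.89 ± 0.171 (adjusted p = 0.038).

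Because the congenic segment lies on chromosome 2, the called genes were counted by chromosome. Pla2g12a, Celsr2, Gstm7, Gstm1 and Chd1l made 5 called genes among 691 tested on chromosome 2, against Wsb1 alone among 9759 elsewhere. The odds ratio was 71.1 (95% interval 7.93 to 3291), with a two-sided Fisher's exact p of 7.1e-06. Of the 13 different genes named by called probe sets, 12 lay on chromosome 2. Their 13 probe sets went both ways, with 10 lower and 3 higher in S.SHR(2). At an unadjusted p under 0.05, 91 of the 691 genes of chromosome 2 (13.2%) differed, against 1.70% to 4.56% on the other autosomes. Pla2g12a, Celsr2, Gstm7 and Gstm1 had no other tested probe set. Probes over bases that differ between the strains could add to these counts, which was not tested.

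In gene order of the assembly GRCr8, the 12 named genes ran from Mecom, the 217th tested gene of chromosome 2, to Pla2g12a, the 605th. That stretch holds 389 of the 691 tested genes, or 56.3%. Among its genes without a call, 64 of 377 (17%) had an unadjusted p under 0.05, against 19 of 302 (6.29%) on the rest of chromosome 2 (odds ratio 3.04, Fisher's exact p = 1.8e-05). On the other chromosomes the share was 352 of 9759 (3.61%). The rest of chromosome 2 also lay above that share (odds ratio 1.79, Fisher's exact p = 0.020). The ends of the stretch were set by the called genes after the values were seen, and neighbouring genes are not independent. No strain genotypes were analysed here, so the borders of the introgressed segment were not determined.

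**Figure D2:**
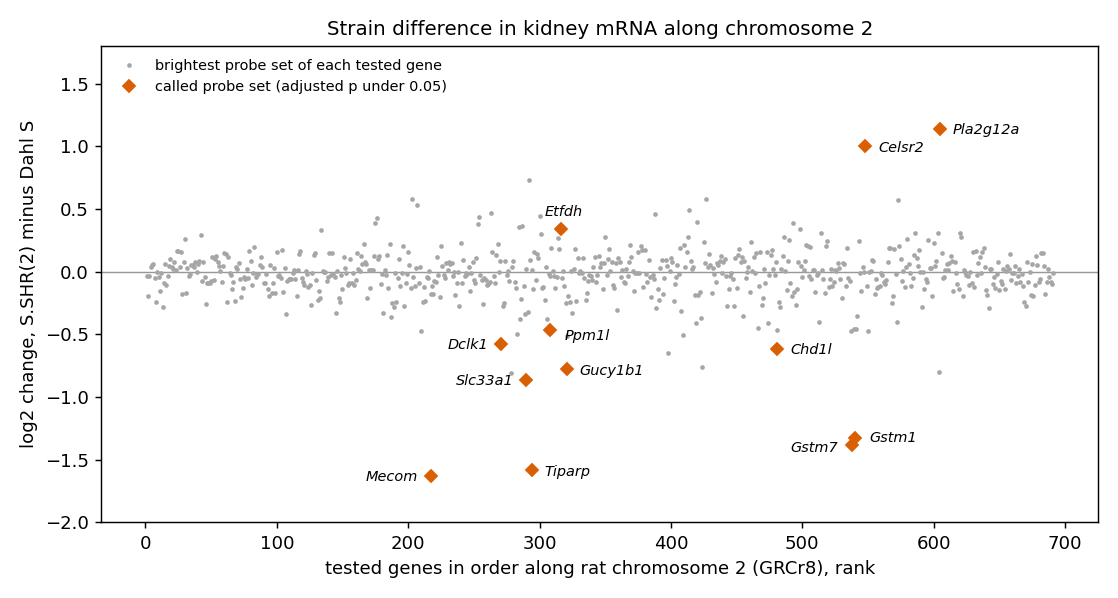
Log2 change (S.SHR(2) minus Dahl S, 9 rats each) against the rank of 691 tested genes along chromosome 2 of GRCr8; grey points show the brightest probe set of each gene and orange diamonds the strongest called probe set of the 12 named genes. The called genes lie between ranks 217 and 605, and for Mecom, Tiparp, Slc33a1 and Ppm1l the grey point of the brightest probe set lies near 0.

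Genes of chromosome 2 proposed as candidates in rat blood pressure and kidney genetics were lower as a list in S.SHR(2), in part through Gstm genes. Of 17 tested, 10 were below 0 and 7 above, with a median log2 change of −0.08 and a mean of −0.19. Of the 10, Gstm1 (−1.33), Gstm5 and Gstm2 are paralogs whose signals cannot be separated here. The list was not tested without them. In the fit without covariates Gstm1 alone passed over all genes. Adjusted over the list alone, 4 were lower: Gstm1 (adjusted p = 1.8e-06), Gucy1b1 (log2 change −0.51 ± 0.118 SE, adjusted p = 0.0026), Gstm5 (−0.48 ± 0.127) and Mme (−0.34 ± 0.088), both at an adjusted p of 0.0052. Mme encodes neprilysin, a peptidase that degrades natriuretic peptides. The natriuretic peptide receptor Npr1 (0.21 ± 0.138), the angiotensin receptor Agtr1b (0.05 ± 0.20), the aminopeptidase Enpep (0.23 ± 0.110), Egf (0.09 ± 0.093), Gucy1a1 (−0.19 ± 0.075), Gstm2 (−0.46 ± 0.230), Gclm (0.11 ± 0.092) and Vcam1 (−0.25 ± 0.156) did not pass. The sign of Agtr1b turned without S.SHR(2) replicate 1 (−0.06) and without Dahl S replicate 7 (−0.05). The list passed camera with the preset correlation (adjusted p = 4.8e-05) and with an estimated correlation (adjusted p = 0.0026). Its score per rat was 0.10 ± 0.091 in Dahl S and −0.10 ± 0.059 in S.SHR(2) (SD, n = 9 each, exact permutation p = 2.1e-04). All 17 genes lie on chromosome 2, so the list repeats in part the count by chromosome.

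Markers of tubular injury, such as vimentin (Vim) and ceruloplasmin (Cp), passed the list test with a lower level in S.SHR(2), but with a difference smaller than the spread between rats. Of 25 tested, 23 were below 0, with a median log2 change of −0.20, and none was called in the fit without covariates. Of the 25, 5 lie on chromosome 2, Cp among them. Cp was at −0.28 ± 0.14, Vim at −0.25 ± 0.151 and Krt19 at 0.21 ± 0.132 (SE). Camera gave an adjusted p of 1.3e-04 with the preset correlation and an adjusted p of 0.73 with an estimated correlation. The score per rat was 0.10 ± 0.573 in Dahl S and −0.10 ± 0.424 in S.SHR(2) (SD, n = 9 each, exact permutation p = 0.42). Without Dahl S replicate 7 the difference in score went from −0.19 to −0.08. The score followed the first component of the variation within strains, which held 88.7% of its variance there. With 1 and 3 residual components as covariates the adjusted p with an estimated correlation was 0.22 and 0.19. The member Spp1 was called as lower in both of these fits (log2 change −0.53, limma adjusted p = 0.033 and 0.0031). Clu was called as lower with 3 components (−0.35, limma adjusted p = 0.045). Spp1 and Clu were picked after their values were seen.

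**Figure D3:**
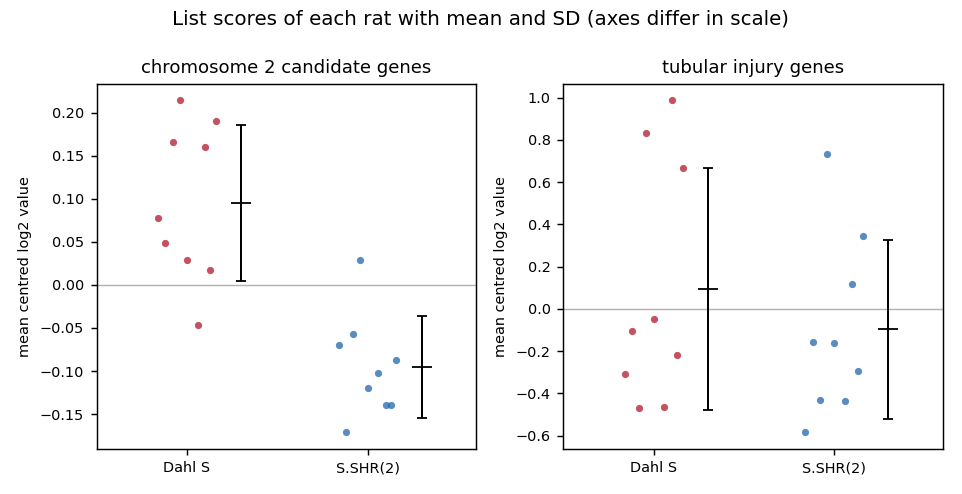
Mean centred log2 value of the chromosome 2 candidate genes (left) and the tubular injury genes (right) in each of 9 Dahl S (red) and 9 S.SHR(2) (blue) kidneys, with mean and SD as black bars; the axes differ in scale. The mean candidate scores differed by more than the SD of either strain. Single rats overlapped, with S.SHR(2) replicate 8 at 0.03 and Dahl S replicate 2 at −0.05. The injury scores, from −0.58 to 0.99, overlapped more widely.

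Matrix, immune and vascular lists went the same way, with the same limit. Extracellular matrix genes had a median of −0.13, with 31 of 36 below 0 and none called. Dcn was at −0.23 ± 0.088, Lum at −0.33 ± 0.163 and Col6a2 at −0.33 ± 0.184. The list had an adjusted p of 1.3e-04 with the preset correlation and an adjusted p of 0.62 with an estimated correlation. Antigen presentation and interferon genes had a median of −0.07, with 29 of 36 below 0, among them Ifi27 (−0.48 ± 0.210), Irf7 (−0.28 ± 0.136) and Gbp2 (−0.29 ± 0.182). Their adjusted p was 6.2e-04, and the adjusted p with an estimated correlation was 0.62. Macrophage genes had a median of −0.12, with 20 of 23 below 0, such as C1qb (−0.30 ± 0.173) and Mrc1 (−0.25 ± 0.135). Their adjusted p was 0.0069, and the adjusted p with an estimated correlation was 0.74. Vascular smooth muscle genes, with Cald1 at −0.24 ± 0.129 and Rgs5 at −0.22 ± 0.115, had 12 of 15 below 0 (adjusted p = 0.0046, and adjusted p = 0.62 with an estimated correlation). Complement and coagulation genes had 16 of 21 below 0, with Cfi at −0.81 ± 0.320 and F5 at −0.30 ± 0.145 (adjusted p = 0.023, and adjusted p = 0.73 with an estimated correlation). In the fit without covariates no member of these lists was called over all genes or adjusted over the list alone. Cfi was called as lower with 3 residual components as covariates (log2 change −0.81, limma adjusted p = 0.018). The complement list was not called without a filter on dim probe sets (adjusted p = 0.10) or with 60% of them left out (adjusted p = 0.075), nor was the vascular list with 60% left out (adjusted p = 0.063). Without the 2 arrays of highest GAPDH 3′/5′ ratio, a fit chosen after the data were seen, the complement and macrophage lists were not called (adjusted p = 0.35 and 0.061). Fits without 1 rat lost the complement list in 9 of 18 cases, the macrophage list in 6, the vascular list without Dahl S replicate 1 (adjusted p = 0.097) and the antigen list without S.SHR(2) replicate 2 (adjusted p = 0.060).

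The oxidative stress and glutathione list passed as lower (adjusted p = 0.042, and adjusted p = 0.62 with an estimated correlation), through Gstm genes of chromosome 2. Its median was 0.02 and its mean −0.09, so that the median differed in sign from the mean and the test, and 22 of 39 members were above 0. Gstm7 and Gstm1 were called over all genes, and Gstm4 (−0.46 ± 0.106) and Gstm5 passed as well when adjusted over the list alone (adjusted p = 0.0042 and 0.012). The list was not called with values as deposited (adjusted p = 0.29), with arrays centred on their medians (adjusted p = 0.21), without a filter on dim probe sets (adjusted p = 0.11) or with 60% of them left out (adjusted p = 0.18). With 1 and 3 residual components as covariates its adjusted p was 0.051 and 0.12, and the call was lost in 10 of the 18 fits that left out 1 rat each.

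The other lists, of kidney cell types, proliferation and metabolism, did not pass camera, with adjusted p values from 0.053 to 0.91. Podocyte genes had a median of 0.00 (17 tested, with Ptpro at 0.14 ± 0.092 and Cd2ap at −0.25 ± 0.132). Proximal tubule genes had a median of 0.02 (31 tested, with Slc22a6 at 0.13 ± 0.053), and thick ascending limb genes 0.01 (13 tested, with Kcnj1 at −0.30 ± 0.161). The distal tubule list had a median of −0.09 over 11 genes and the collecting duct list 0.02 over 22 genes, with Sgk1 at −0.21 ± 0.116. The distal tubule list passed as lower with 1 and 3 residual components as covariates (adjusted p = 0.029 and 0.016), though not with an estimated correlation (adjusted p = 0.22 and 0.19). In the renin-angiotensin-aldosterone list Mme passed when adjusted over the list alone (adjusted p = 0.015), and Agtr1a was at 0.14 ± 0.096. In the fatty acid oxidation list Etfdh passed in the same way (adjusted p = 0.0016), and Ppargc1a was at −0.26 ± 0.104. The cell cycle list, with Cenpf at −0.28 ± 0.115 and Prc1 at −0.27 ± 0.128, had an adjusted p of 0.053, and the lymphocyte list 0.060. The median of the xenobiotic list was 0.04, with Nat8 at 0.20 ± 0.076. The other lists tested, of chemokines, vasoactive factors, oxidative phosphorylation, cholesterol synthesis, endothelium and immediate early genes, had adjusted p values from 0.26 to 0.90. The alternatives changed some of these calls. With values as deposited and with arrays centred on their medians, the oxidative phosphorylation list passed as higher (adjusted p = 0.0053 and 7.3e-04). The cell cycle (adjusted p = 0.022 and 0.0063) and lymphocyte (adjusted p = 0.022 and 0.0089) lists passed as lower, and proximal tubule genes passed as higher with centred arrays (adjusted p = 0.029). Both the cell cycle and the lymphocyte list also passed with array weights (adjusted p = 0.024 and 0.027), with 1 residual component (adjusted p = 0.032 for each), and in 6 and 7 of the 18 fits without 1 rat. With 1 component and an estimated correlation neither passed (adjusted p = 0.57 and 0.22). The cell cycle list passed further with a pseudocount of 1 (adjusted p = 0.041), without a filter (adjusted p = 0.042) and without the 2 arrays of highest GAPDH ratio (adjusted p = 0.0031). In that last fit the distal tubule and endothelium lists passed as lower too (adjusted p = 0.034 for each).

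Markers of neighbouring tissue did not separate the strains. Adipose and liver lists had adjusted p values of 0.90 and 0.27. The adrenal and red blood cell lists had 2 and 3 tested genes, too few for a test, with Cyp11a1 at −0.22 ± 0.120 and Hbb at −0.37 ± 0.280. Of the Y-linked genes, Eif2s3y was at −0.25 ± 0.111 with an unadjusted p of 0.033. As a sign of RNA quality, the beta-actin 3′/5′ ratio ran from 2.22 to 6.83 over the arrays, and its log2 value differed between the strains by 0.15 (exact permutation p = 0.49).

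Most variation in these kidneys lay within the strains. The strain means held 4.56% of the total variance of the tested probe sets. Groupings of the arrays at random hold a share as well, which was not computed, so this value alone does not measure a strain effect. After the strain means were removed, the first 3 components of the residuals held 41.7%, 16.2% and 8.18% of what was left. The arrays fell into separate clusters, and each held rats of both strains. No rat was assigned an age from these values.

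**Figure D4:**
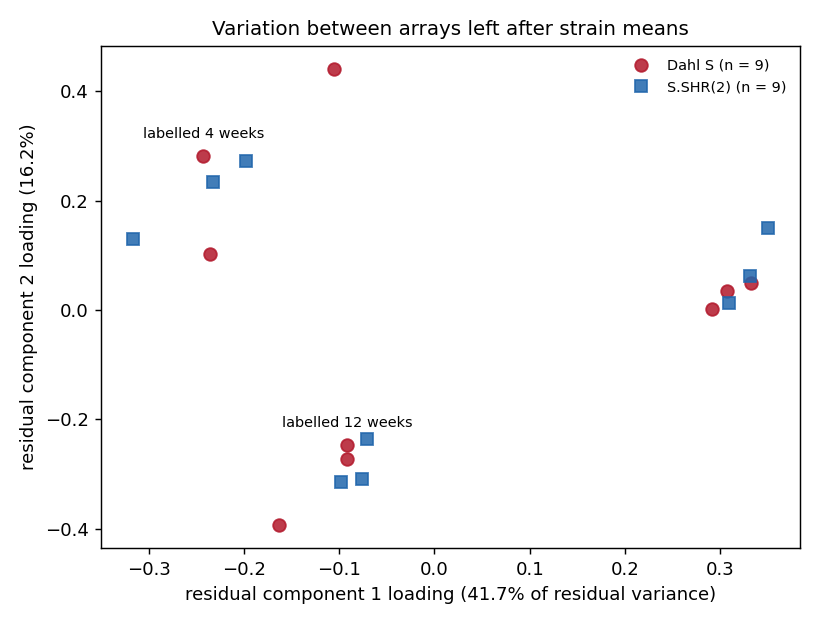
Loadings of the 9 Dahl S (circles) and 9 S.SHR(2) (squares) arrays on the first and second components of the residuals, which held 41.7% and 16.2% of the residual variance; the Dahl S rats whose labels give 4 and 12 weeks are marked. On component 1, 6 arrays lie between 0.29 and 0.35 and the other 12 between −0.32 and −0.07.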

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

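The comparison between probe sets of 1 gene and the leave-out, component and permutation tests of the injury score were chosen after the values were seen, and the fit of that score with the beta-actin ratio before its result was. Tests for single rats far from the other 8 of their strain covered 180 groups of values, of which chance alone would single out about 9, and 12 were singled out.

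Several of these concerned few rats. S.SHR(2) replicate 8 had the highest Vim and Krt19 of its strain, with log2 values of 10.04 and 8.38 against at most 9.47 and 7.76 in the other rats, and an immediate early and heat shock score of 0.55 against at most 0.09. S.SHR(2) replicate 1 had a log2 value of 6.61 for Mrc1, above the others at 5.79 to 6.20, and the lowest Eif2s3y, at 8.44 against 8.85 to 9.24. Its GAPDH 3′/5′ ratio of 2.51 was also above the others, at 1.27 to 1.74. Dahl S replicate 5 had the highest beta-actin and GAPDH 3′/5′ ratios of its strain, 5.88 and 2.04, and the lowest oxidative stress and glutathione score, −0.15 against 0.01 to 0.16. S.SHR(2) replicate 5 had the highest Slc22a6, at 11.59 against 11.23 to 11.39. S.SHR(2) replicate 7 had a fatty acid oxidation score of 0.084 against at most 0.029. Dahl S replicate 3 had the lowest Bmal1, at 6.21 against 6.81 to 7.25.

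Some called genes of chromosome 2 gave different values with different probe sets. A probe that covers bases differing between the strains could bind less well in one of them and mimic a change of mRNA. Over the 8 other tested probe sets of 7 called genes, the median change in the direction of the called one was 0.106, with members on both sides of it, which decides nothing for the set. Adjusted over these 8, the other probe sets of Chd1l, Gucy1b1 and Dclk1 were lower too (limma adjusted p = 4.2e-05, 0.0012 and 0.024), so for these genes the difference was not confined to 1 probe set. The change of the called probe set differed from that of the other for Tiparp (by −1.60), Mecom (−1.45) and Slc33a1 (−0.89 and −0.87). Their exact permutation adjusted p values were 3.3e-04 to 4.1e-04. Ppm1l differed by −0.43 (exact permutation adjusted p = 0.017). For Gucy1b1, Dclk1 and Chd1l that adjusted p was 0.066 to 0.088. The called probe set was taken as the one of smallest p on these same rats. That choice favours a difference, and these p values do not allow for it. Differing bases, transcript forms and a strain difference in the mRNA cannot be told apart for the set, because no probe or strain sequences were used here. The 5 called genes Pla2g12a, Celsr2, Gstm7, Gstm1 and Etfdh had no other tested probe set, so each of these changes rests on 1 probe set.

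The injury score of the rats followed the first residual component more than the strain. The 6 arrays above 0.29 on that component had scores of 0.99, 0.83 and 0.67 in Dahl S and 0.12, 0.73 and 0.34 in S.SHR(2), and the other 12 lay between −0.58 and −0.05. The exact permutation p of 0.42 came from splits that ignore this structure, so it neither excludes chance nor shows that chance could account for the lower list in S.SHR(2). The score difference of −0.19 was −0.0811 without Dahl S replicate 7. With component 1 as a covariate it was −0.19 ± 0.082 (SE, against 0.238 without it) and lay between −0.22 and −0.14 whichever rat was left out. The component was taken from the same values after strain means were removed, so with all rats it could change only the error. The component of all rats also served when 1 rat was left out, so these fits cannot decide the part of single rats, which stays open. With the log2 beta-actin 3′/5′ ratio as a covariate the difference was −0.101 ± 0.210 (SE), too uncertain to tell whether RNA quality had a part, and a strain difference limited to 1 age stays open and untested, since most ages are unlabelled.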

How the results depend on the processing

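The alternatives without the 2 arrays of highest GAPDH 3′/5′ ratio and with the beta-actin ratio as a covariate were chosen after seeing the data. The direction of the chromosome 2 enrichment and its side of the threshold held under all 31 alternatives, with odds ratios from 14.3 to 172 and Fisher's exact p at most 2.4e-05. Pla2g12a, Celsr2, Gstm7, Gstm1 and Wsb1 stayed past the threshold in all 30 alternatives run for single genes, with Pla2g12a at 0.88 to 1.26 and Gstm7 at −1.65 to −0.93. The 6 called genes became 11 with values as deposited, 19 with array weights, 29 with 1 residual component, 107 with 3, 10 with the mean of a gene's probe sets and 14 with the beta-actin ratio as a covariate. The 23 called probe sets became 41 with array weights, 64 with 1 residual component and 175 with 3. The number of lists called went from 8 to 5 with 60% of probe sets left out, where fewer genes were tested, and to 1 with an estimated correlation. The oxidative stress list lost its call with no filter, with 60% left out, with values as deposited, with centred arrays and with 1 or 3 residual components, and the complement list with no filter, with 60% left out and without the 2 arrays of highest GAPDH ratio, where the macrophage list lost its call too. The cell cycle list gained a call under 7 alternatives other than leaving out 1 rat and the lymphocyte list under 4. Apart from the fits with fewer genes, the cause was not tested. Leaving out 1 rat at a time gave 16 to 28 probe sets, 6 to 13 genes and 5 to 10 lists, with the complement list lost in 9 of these fits and the macrophage list in 6, 13 genes without Dahl S replicate 1 and 5 lists without S.SHR(2) replicate 2 or Dahl S replicate 8. Agtr1b, which was not called, turned from 0.052 to −0.060 without S.SHR(2) replicate 1, to −0.049 without Dahl S replicate 7 and to −0.028 without the 2 arrays of highest GAPDH ratio, with 0.14 as the highest value when 1 rat was left out, and the cause was not tested. No paired analysis was run, because the labels give the rats of the strains no shared numbers. A fit with a block for the order in which the samples were deposited was not run either. Signal over background limits dim genes most, since no detection calls were used here.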

Other observations

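The list of clock genes and its permutation test, the place of the clock genes, the comparison of their sides and the splits at an unadjusted p were chosen after the values were seen. The remaining splits of the arrays and the fits with the beta-actin ratio were set before their results were seen.

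With the first residual component as a covariate, 29 genes were called, of which 23 lay on chromosome 2, 11 higher and 12 lower in S.SHR(2). The Fisher's exact p for chromosome 2 was 1.7e-22. Genes that joined the list included S100a10, an annexin A2 ligand (log2 change −0.76 ± 0.114 SE, limma adjusted p = 0.0020), Il6r, the interleukin-6 receptor (−0.65 ± 0.118, adjusted p = 0.013), Tsc22d2 (−0.81 ± 0.147, adjusted p = 0.013) and the phospholipase D gene Pld1 (0.53 ± 0.085, adjusted p = 0.0041). These genes were chosen after their values were seen, and in the fit without the component their adjusted p values were 0.61, 0.097, 0.999 and 0.084. Other splits of the arrays were not run with 1 component. With 3 components 107 genes were called, 52 on chromosome 2 and 55 elsewhere (odds ratio 14.3, Fisher's exact p = 2.8e-33). Of the 52, 26 were higher and 26 lower.

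Strain assignments drawn at random, 100 splits of the 18 arrays into 9 and 9 with the real one included, served as a test of chance. As many called probe sets as the real 23 came in 3 splits, the real one among them, with 3179 in the highest other. As many genes as the real 6 came likewise in 3 splits, with 1269 in the highest other. Both counts were thus rare among these splits, but the splits ignore the structure of the samples, so chance was not excluded. For the chromosome 2 enrichment of called genes the real −log10 p was 5.15, against 0.0918 in the highest other, but 97 of the 99 other splits called no gene, so this only repeats the count of genes. At an unadjusted p under 0.05, an odds ratio for chromosome 2 as large as the real 4.05 came in 2 splits, the real one among them. The highest other was 4.21, in a split with 2 Dahl S arrays in its first group of 9, which thus kept the strains largely apart. The next highest, 3.13 and 2.85, came from splits with 7 and 8 Dahl S arrays in that group. Such a value was rare among these splits, with the same limit. For the number of lists called, 34 splits gave 8 or more and the highest other gave 13. With 3 residual components, 61 splits gave 175 or more probe sets and the highest other gave 6770. Splits that mix the clusters of arrays unevenly can call lists and probe sets through the clusters. Chance was therefore neither excluded nor shown for the count of lists and for the count with 3 components. Splits that call many times the real count point to a structure of the samples.

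That structure shows in the residual components. On component 1, Dahl S replicates 7, 8 and 9 were at 0.33, 0.29 and 0.31 and S.SHR(2) replicates 7, 8 and 9 at 0.31, 0.35 and 0.33, while the other 12 arrays were between −0.32 and −0.07. On component 2, Dahl S replicates 4, 5 and 6 were at −0.25, −0.39 and −0.27 and S.SHR(2) replicates 4, 5 and 6 at −0.31, −0.31 and −0.24, while the others were between 0.00 and 0.44. The highest deposited intensity on an array was 7508 to 9499 on the 6 arrays above 0.29 on component 1 and 11117 to 14648 on the other 12. No age was inferred from these values.

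Genes of the circadian clock lay on opposite sides of 0, a pattern noticed in the data. Bmal1, Clock, Npas2, Cry1 and Nfil3 were placed on the side of Bmal1, and Dbp, Nr1d1, Nr1d2, Per1, Per2, Per3, Tef, Hlf, Bhlhe40, Bhlhe41 and Cry2 on that of Dbp, after the values were seen. Cry1 and Nfil3 are repressors, so the sides are not activators and targets. Bmal1, the clock activator, was at −0.53 ± 0.117 (SE) in S.SHR(2), whereas Dbp was at 0.86 ± 0.210, Nr1d1 at 0.62 ± 0.169 and Per2 at 0.41 ± 0.143. None of 16 clock genes passed limma's adjusted p of 0.05 over all genes, with Bmal1 at 0.11 and Dbp at 0.21. Bmal1 passed with 1 residual component as a covariate (adjusted p = 0.023), and Bmal1, Dbp and Nr1d1 passed with 3 (adjusted p = 0.0074, 1.2e-04 and 0.0090). Of the 16, 15 went the way of their side, with Bhlhe40 as the exception, though the sides were set after the values were seen. The score of the Dbp side minus the Bmal1 side was −0.35 ± 0.476 in Dahl S and 0.35 ± 0.313 in S.SHR(2) (SD, n = 9 each, exact permutation p = 0.0021), and without Cry1 and Nfil3 the difference went from 0.69 to 0.66 (exact permutation p = 0.0029).

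Multiplied by the 27 lists scored, the p of the clock score is 0.057, but these splits ignore the structure of the samples and the correction does not cover a choice of genes made from their values, so chance was neither excluded nor shown. RNA quality as the whole cause is argued against by a score difference of 0.731 ± 0.192 (SE) with the beta-actin ratio as a covariate, against 0.69 without it. None of the 16 lies on chromosome 2. Of 25 clock and clock-related genes tested, 1 does and had an unadjusted p under 0.05, Noct (0.43 ± 0.185 SE, limma adjusted p = 0.999). Noct was called as higher in the fit with residual components in which Dbp and Nr1d1 passed (0.43 ± 0.103 SE, limma adjusted p = 0.040). Clock genes inside the chromosome 2 segment therefore stay open as a cause. Kidneys collected at another time of day in one strain could give opposite sides, as seen in the difference of 0.693 between them, and cannot be told apart from a strain difference in the clock because the labels give no collection times.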
